A study of Mus musculus with 12 samples.

How the data were processed

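The study measured polyadenylated RNA in 12 mouse T-ALL samples of the C57BL/6 strain. Per the labels, the leukaemia carried an activated Notch1 allele, and cells from spleen were kept on OP9 stromal cells, a mouse bone marrow line, with 5 ng/ml of the cytokine IL-7. The labels give this culture for every sample, the primary tumours included. They do not settle whether the tumours were cultured before RNA extraction. Dose and duration of AMD3100 are not given in the sources used here. Libraries were strand-specific (dUTP method) and sequenced as 50-base single reads, per the labels' protocols.

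The values are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library), as the authors deposited them in 2 tables of 6 samples each. Per the submitters' processing notes the tools were CASAVA and TopHat and the genome build was mm9. The program and annotation that produced the FPKM values, their versions and whether the counting used strand are not given in the sources used here. Each table held 23174 genes under the same symbols. Of these, 175 symbols stood on more than 1 line (447 lines in all), 191 entries joined several symbols, and 685 were small RNAs, which poly-A selection of long RNA captures poorly. A further 26 symbols were date-like, such as a spreadsheet makes of gene names. Gapdh, a gene used by every cell, was listed at or near 0 in all libraries, so a value of 0 may be a failed estimate, and genes are only said to be listed at 0. Every column was matched to its sample by name. No coordinates are given, because no annotation of build mm9 was used here.

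FPKM values are not counts, so tests were run on log2(FPKM + 1). Genes with a mean of at least 1 FPKM over the 6 samples of a table were kept, 10245 ex vivo and 10741 in the tumours. Each comparison was fitted alone with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean trend, two-sided), with Benjamini-Hochberg adjustment over the kept genes and a call at an adjusted p under 0.05. Gene lists with 3 or more kept members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, which asks whether a list's genes move one way on balance without comparing them with other genes. An exact permutation test of 3 samples against 3 cannot give a p under 0.1, so single values were tested only within the models across genes. The main design, the 29 gene lists, the rule for named genes and most alternatives were set before the data were examined.

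The ex vivo groups share replicate numbers, and the main fit had no block. Same-numbered samples deviated together from their group means, with correlations of 0.467, 0.579 and 0.619 for the 3 pairs, all above the limit of 0.1 set beforehand, so the numbers were taken as pairs and the fit with the replicate number as a block is reported beside the main one. The pairing rests on these values and the shared numbers, since the labels do not say what the number marks. Vehicle and AMD3100 samples with different numbers had correlations from -0.473 to 0.0455. Tumours of different genotype reached 0.505 (wild type 1 and knockout 7) and 0.534 (wild type 4 and knockout 5). A value of this size alone therefore does not show a pair. The tumours share no numbers between genotypes.

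The rule for named genes took Cxcr4, Cxcr7, Cxcl12, Myc, Notch1, Hes1, Dtx1, Il7r, Klf2 and S1pr1, the 8 largest rises and 8 largest falls among called annotated genes whose groups do not overlap, and for each called list (and always for the Myc, Notch1, G1/S, G2/M and homing lists) the 3 members with the smallest p. Not every gene that the rule names is reported here. Applying the same rule of 8 to the paired calls was added after the values were seen. The lists were CXCL12 receptors and ligand, Myc targets of growth and nucleolus, Notch1 targets, leukaemia-initiating and early progenitor genes, T cell receptor and coreceptor genes, recombination and double-positive thymocyte genes, homing, adhesion and egress, FoxO and PI3K-Akt responsive genes, G1/S and DNA replication, G2/M and mitosis, cytosolic ribosomal proteins, oxidative phosphorylation, glycolysis and hypoxia, cholesterol and fatty acid synthesis, amino acid and ER stress, p53 targets and apoptosis, interferon response, immediate early and NF-kB genes, heat shock genes and sex-linked genes. Marker lists covered B cells, macrophages, neutrophils, erythroid cells, NK and cytotoxic cells, dendritic cells, platelets, stroma and endothelium. Some genes stand in several lists, such as Pcna, Klf2 and S1pr1.

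Alternatives were other pseudocounts (0.1 and 0.5), other filters (0.1 FPKM, none, 5 FPKM), median-of-ratios, TMM and quantile scaling, other variance models, an adjusted p under 0.10, a log2 change of at least 1, leaving out each library, and the block. Alternatives chosen after seeing the data were leaving out small RNAs, paired fits with other settings or without a pair, paired fits corrected for transcript length or GC content, and 3 that deal with red cell RNA or T cell content of the tumours. Lengths and GC content came from the longest transcript per symbol in GENCODE release M21, which is built on another genome assembly than the authors', and 98.4% of the ex vivo genes had a value. Tables were handled in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.

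The code was tested on simulated data made from the real genes' means and spreads. Ex vivo (10245 genes), 63 of 100 genes changed by 1 on the log2 scale were recovered without the block and 94 with it, 88 and 100 of 100 at a change of 2, and 0 and 9 unchanged genes were called. In the tumours (10741 genes), 2 of 100 were recovered at a change of 1, 37 at 2 and 84 at 4, with 12 unchanged genes called. With an added covariate effect, the fit with that covariate recovered 17 of 100 tumour genes at a change of 2 and the fit without it 2. Camera called the 1 moved list and none of 20 unmoved lists in each comparison (lists of 40 independent genes). Members of the real lists were not independent, with estimated correlations for G1/S of 0.148 ex vivo and 0.891 in the tumours. The simulation therefore does not show how often camera calls unmoved lists of such genes. After a simulated length trend the correction brought the Spearman correlation with length from 0.899 to 0.00907 and the unchanged genes called from 4942 to 12. Relative depth ex vivo came from the most common ratio of low values between libraries, shared by 35.6% to 45.4% of the genes used.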

Results

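Gene expression was measured by RNA sequencing in mouse T cell acute lymphoblastic leukaemia (T-ALL), a cancer of immature T cells, driven here by an activated form of Notch1 that lacks most of its extracellular part. In the ex vivo experiment, leukaemia cells from spleen received AMD3100, a small molecule that blocks the chemokine receptor CXCR4, or vehicle, with 3 samples each. In the other experiment, 3 primary tumours with intact Cxcr4 were compared with 3 tumours in which Cxcr4 was knocked out. Both comparisons ask what leukaemia cells express when the receptor for the chemokine CXCL12 is blocked or missing. The 2 tables of FPKM values were analysed separately, so levels are compared only within a table. The labels do not say that samples of a group came from separate animals or cultures. The p-values therefore measure only the spread between these samples, which may be technical ex vivo. Among the tumours, haemoglobin genes took 1.29% to 23.0% of the summed FPKM in wild type and 2.76% to 20.4% in knockout. This argues against a purely technical spread there.

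Summed FPKM per library ran from 444803 to 480468 ex vivo and from 368118 to 581159 in the tumours. FPKM values do not give the read totals, but the steps between the lowest values gave a relative depth ex vivo. Against the first vehicle library this was 0.908 and 0.758 for the other vehicle libraries and 1.06, 1.25 and 1.21 for the AMD3100 libraries. Too few low values remained in the tumours for such an estimate, and knockout tumour 8 had 13231 genes listed at 0, the most of any library. Spearman correlations between libraries of a group ran from 0.942 to 0.962 ex vivo and from 0.909 to 0.946 in the tumours. In the ex vivo libraries haemoglobin genes took at most 0.000139% of the summed FPKM. In wild-type tumours 1, 2 and 4, haemoglobin genes took 1.29%, 5.47% and 23.0% of the summed FPKM. In knockout tumours 5, 7 and 8 the shares were 20.4%, 2.76% and 6.55%. Cxcl12, a gene of the stromal marker list, was listed at 0 in every tumour and at 3.84 to 15.9 FPKM ex vivo. These values argue against the tumours having been kept as the ex vivo cells were, although 0 may be a failed estimate.

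With AMD3100, genes of cholesterol and fatty acid synthesis (24 of 32) and of DNA replication (35 of 44) fell in the T-ALL cells, and genes of the amino acid and ER stress response (15 of 29) rose, with same-numbered samples paired. Without pairing, limma called 1 of the 32, 0 of the 44 and 0 of the 29 members. Camera called these 3 lists with and without pairing at its preset correlation. With an estimated correlation it called none of them (adjusted p = 0.291, 0.291 and 0.307 without pairing and 0.610 for each with pairing). Scd1, which encodes the stearoyl-CoA desaturase that makes monounsaturated fatty acids, fell from 19.5 ± 3.62 to 2.73 ± 0.673 FPKM (SD, n = 3), a log2 change of -2.46 (SE 0.21, adjusted p = 0.0383 in limma). Dbi, an acyl-CoA binding protein, fell from 329 ± 12.9 to 168 ± 8.80 FPKM, and the histone H3 gene Hist1h3c from 123 ± 8.92 to 60.7 ± 2.77 FPKM. With the replicate number as a block, Trib3, a pseudokinase induced by the ATF4 pathway, rose from 3.75 ± 0.699 to 34.8 ± 26.5 FPKM, a log2 change of 2.64 (paired SE 0.40, adjusted p = 0.0221). All fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values.

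Without the block, limma called 13 of 10245 genes, 5 higher and 8 lower, at an adjusted p under 0.05, and 2204 genes had an unadjusted p under 0.05. With the same-numbered vehicle and AMD3100 samples paired it called 2036 genes, 1020 higher and 1016 lower, with all 13 among them. Of the 2036 genes, 134 changed at least 2-fold, 95 upward and 39 downward. The groups did not overlap for 28.9% of the genes, where chance gives 10%. The paired count was 9 without the samples numbered 1, 7 without those numbered 2 and 1207 without those numbered 3. The unpaired count fell to between 3 and 5 without any single library, and other scalings moved its split from 5 higher and 8 lower to 24 and 65 with median-of-ratios factors and to 2 and 1 with quantile normalisation.

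Among the 13, the higher genes were Rnf169 (log2 0.93), a ubiquitin-binding factor of the DNA damage response, Eif2c2 (log2 0.82), the Argonaute protein also known as Ago2, and 3 small or predicted transcripts. Mir1931 was listed at 0 in all vehicle libraries and at 69.0, 87.9 and 60.6 FPKM with AMD3100, and Mir1190 was listed at 0 in all vehicle libraries and at 64.4, 54.7 and 283 FPKM. The lower genes besides Scd1, Dbi and Hist1h3c were the histone gene Hist1h2bj (log2 -0.85), Deb1 (log2 -0.93), the RNA export factor Nxt1 (log2 -0.81), the prolyl isomerase Fkbp3 (log2 -0.79) and the predicted gene BC002163 (log2 -0.83). BC002163 and the predicted transcript Gm12238, listed at 0 in the vehicle libraries and at 29.1, 98.8 and 76.6 FPKM with AMD3100, were named after their values were seen. FPKM divides by transcript length, so a few reads on a very short transcript give a high value. The AMD3100 libraries were also deeper, at 1.06, 1.25 and 1.21 against 0.908 and 0.758 for vehicle 2 and 3, relative to vehicle 1. The reads behind Mir1931, Mir1190 and Gm12238 are not known, so their changes may lie near the limit of detection.

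The largest paired rises among annotated genes after Trib3 were those of Atf5, a stress-induced transcription factor (log2 2.33), the cationic amino acid transporter Slc7a3 (log2 2.28), the activation marker Cd69 (log2 1.81), the glutathione-degrading enzyme Chac1 (log2 1.80) and Fam102a (log2 1.80). The largest paired falls after Scd1 were those of Fam178b (log2 -1.68), the mevalonate pathway kinase Pmvk (log2 -1.65), the thioredoxin-interacting protein Txnip (log2 -1.51), the RNA component Rmrp of RNase MRP (log2 -1.43) and the histone genes Hist1h2bm, Hist1h3b and Hist1h2bf (log2 -1.40, -1.39 and -1.39). Histone genes have near-identical copies, and their values are uncertain where reads could be shared between copies.

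**Figure D1:**
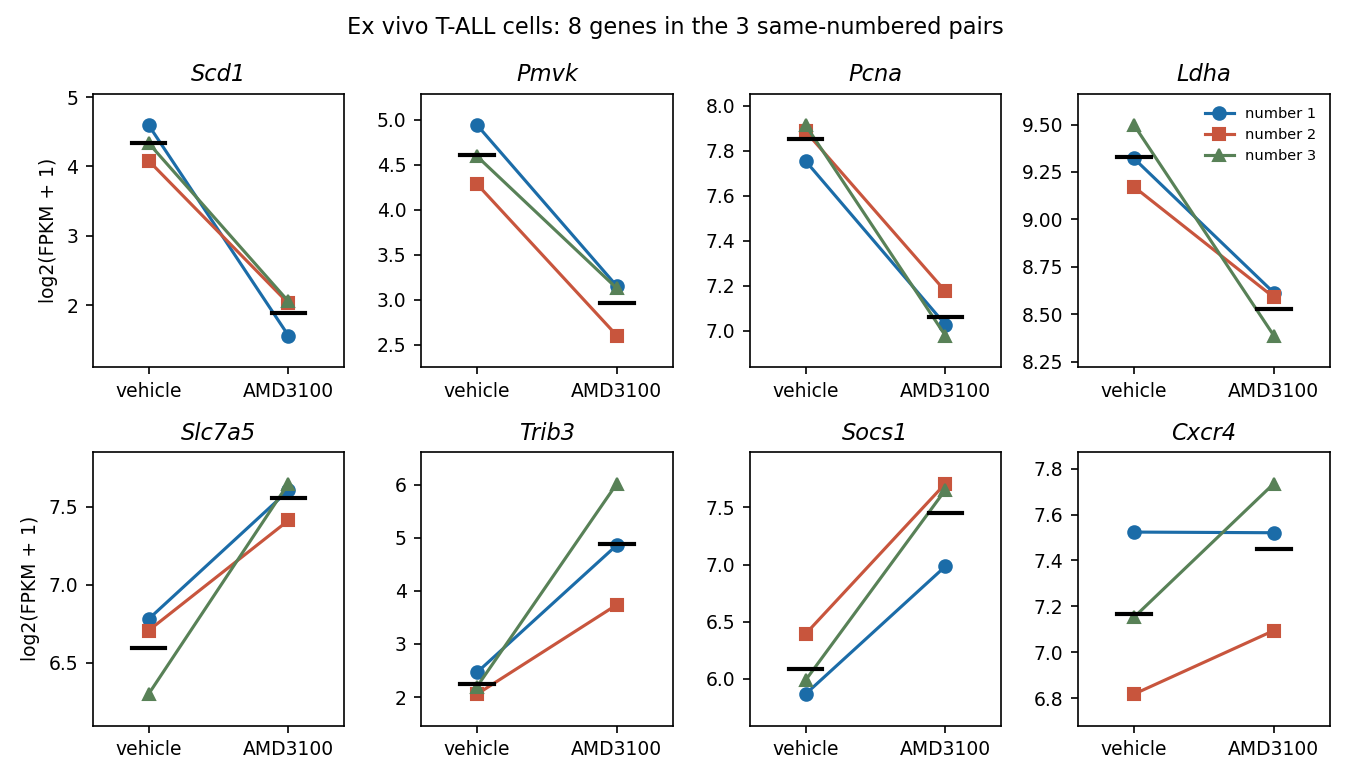
Expression as log2(FPKM + 1) of 8 genes in vehicle and AMD3100 samples of T-ALL cells, with lines joining the 3 same-numbered pairs and black bars at the group means. Scd1, Pmvk, Pcna and Ldha are lower and Slc7a5, Trib3 and Socs1 are higher with AMD3100 in 3 of 3 pairs, while Cxcr4 is higher in 2 of 3.

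The cholesterol and fatty acid synthesis genes, most of them targets of SREBP transcription factors, had the lowest median of the lists with 3 or more measured members, a log2 change of -0.61 over 32 members. In the paired fit 24 members fell, none rose and 8 were not called, with 30 lower when adjusted over the list alone. Member counts of the ex vivo lists below are also those of the paired fit. Without pairing, Scd1 was the only list member that limma called over all genes. Besides Scd1, Pmvk fell from 23.8 ± 5.64 to 6.91 ± 1.58 FPKM. The G1/S and DNA replication list had a median of -0.46, and 35 of its 44 members fell and none rose (39 lower adjusted over the list alone). The sliding clamp gene Pcna fell from 230.2 ± 13.4 to 133 ± 9.65 FPKM, the DNA ligase gene Lig1 by 0.53 and the primase gene Prim1 by 0.70 on the log2 scale. Camera called both lists lower without pairing (adjusted p = 8.69e-15 and 3.63e-19) and neither with an estimated correlation (adjusted p = 0.291 for each).

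Genes of oxidative phosphorylation had a median of -0.36, and 24 of 53 members fell while 1 rose (38 and 1 adjusted over the list alone). After a correction of each pair for transcript length the median was -0.20, and 9 members fell and 2 rose. Examples were the respiratory chain subunits Ndufa4 (651 ± 96.6 to 348 ± 14.2 FPKM), Uqcrc1 (205 ± 11.1 to 137 ± 7.74 FPKM) and Sdhd (log2 -0.59). Of 50 Myc targets of growth and the nucleolus, 16 fell and 1 rose (22 and 2 adjusted over the list alone), with a median of -0.30, including the lactate dehydrogenase gene Ldha (645 ± 73.3 to 369 ± 31.1 FPKM), Pcna and Wdr74 (log2 -0.68). Of 13 heat shock genes, 4 fell, among them Stip1 (log2 -0.51), Hspa8 (log2 -0.54) and Hspd1 (log2 -0.41), and 1 rose (8 and 3 adjusted over the list alone), with a median of -0.28. Of 39 genes of G2/M and mitosis, 6 fell and none rose (5 lower adjusted over the list alone), with a median of -0.12, among them Birc5 (log2 -0.47), Cdc20 (log2 -0.39) and Ccna2 (log2 -0.32). Camera called these 4 lists lower, and with an estimated correlation their adjusted p was 0.291 for the first 3 and 0.581 for G2/M. The G2/M call was also lost with quantile normalisation and without vehicle 3 or AMD3100 2, and the heat shock call with quantile normalisation and, when paired, without the samples numbered 2.

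Immediate early and NF-kB genes, which respond within hours to receptor signals, had a median of 0.52, and 14 of 37 members rose and none fell (17 higher adjusted over the list alone). The cytokine signalling inhibitor Socs1 rose from 67.6 ± 13.6 to 178 ± 45.6 FPKM, Cd69 from 3.69 ± 0.788 to 16.2 ± 6.32 FPKM and the AP-1 subunit Jund from 29.1 ± 7.40 to 65.5 ± 24.6 FPKM. In the amino acid and ER stress list (median 0.37), 15 of 29 members rose and 3 fell (16 and 5 adjusted over the list alone). Among those that rose, Slc7a5, a large neutral amino acid transporter, rose from 96.7 ± 16.6 to 188 ± 16.1 FPKM, Slc7a3 from 0.648 ± 0.349 to 7.06 ± 2.13 FPKM and Chac1 from 1.97 ± 0.648 to 9.47 ± 3.02 FPKM. The 3 that fell, Creld2 (log2 -0.53), Hsp90b1 (log2 -0.39) and Calr (log2 -0.38), encode proteins of the ER lumen and were named after their values were seen. Camera called both lists higher, and with an estimated correlation their adjusted p was 0.291 and 0.307.

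Homing, adhesion and egress genes had a median of 0.37, with 12 of 27 members higher and none lower (12 higher adjusted over the list alone), among them the integrin genes Itgae (15.6 ± 6.41 to 40.5 ± 16.7 FPKM) and Itgal (99.2 ± 2.17 to 146 ± 23.3 FPKM) and the migration regulator Dock2 (log2 0.38). Klf2, a transcription factor of lymphocyte egress, rose in the paired fit from 10.5 ± 9.16 to 25.4 ± 21.5 FPKM, and its target S1pr1, the sphingosine-1-phosphate receptor, from 2.77 ± 1.97 to 6.04 ± 3.17 FPKM. The unpaired log2 change of Klf2 turned from 1.07 to -0.23 without vehicle 3. Of 32 interferon response genes, 7 rose and none fell (7 higher adjusted over the list alone), with a median of 0.33, including Irf9 (log2 0.96), Irf7 (log2 1.01) and Parp14 (log2 0.42). Of 28 p53 target and apoptosis genes, 6 rose and 2 fell (11 and 2 adjusted over the list alone), with a median of 0.27. Sesn2 (log2 1.20), which also stands in the amino acid and ER stress list, and the survival gene Bcl2l1 (log2 0.44) rose. Ccng1 had a log2 change of 0.44 and was not called. Camera called these 3 lists higher, and with an estimated correlation their adjusted p was 0.291 for homing and p53 and 0.574 for interferon, which also lost its call without AMD3100 3.

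A further 3 lists were called higher by camera in the paired fit and not in the unpaired fit of all 6 samples, and their paired adjusted p was 0.610 with an estimated correlation. Of 23 FoxO and PI3K-Akt responsive genes, 10 rose and 2 fell (11 and 2 adjusted over the list alone). Of 7 measured leukaemia-initiating and early progenitor genes, 3 rose and none fell (3 higher adjusted over the list alone), namely Runx1, Bcl11b and Gata3. The list has 22 genes, and Lmo2, Hhex, Mycn, Tal1, Hoxa9 and Meis1 are among those under the minimum of 1 FPKM. The call therefore does not show a rise of an early progenitor programme. Of 4 NK and cytotoxic markers, 2 rose, Nkg7 and Gzmb (3 higher adjusted over the list alone). Without pairing, camera also called the leukaemia-initiating and NK lists higher without AMD3100 1 and the FoxO list without AMD3100 3. The paired FoxO call was lost without the samples numbered 2 and after a correction for transcript length, and the paired NK call at a mean of 5 FPKM. After the length correction camera still called 8 lists higher and 6 lower, so another list was called higher instead. With paired quantile normalisation it called 10 higher and 4 lower. Not called by camera were the Notch1 targets (7 of 20 higher, 1 lower; 8 and 1 adjusted over the list alone), T cell receptor and coreceptor genes (3 of 22 higher, 1 lower; 5 and 2 adjusted over the list alone), recombination and double-positive thymocyte genes (1 of 14 higher, 1 lower, the same counts adjusted over the list alone), cytosolic ribosomal proteins (1 of 52 higher, 1 lower; 1 and 0 adjusted over the list alone) and genes of glycolysis and hypoxia (5 of 29 higher, 7 lower; 7 and 8 adjusted over the list alone). When single libraries or pairs were left out, camera called the Notch1 targets higher without AMD3100 3, without the samples numbered 1 and without those numbered 3, the T cell receptor list higher without the samples numbered 3 and the ribosomal proteins lower without AMD3100 1. The ribosomal protein median turned from -0.040 to 0.083 after the length correction, with 5 members higher and none lower in the paired fit. Macrophage markers (none of 4 called) and stromal markers (1 of 12 lower, none higher; none adjusted over the list alone) were not called either. Too few members were measured for a list test of B cell markers (1 of 2 higher, Pou2af1), erythroid markers (1 of 2 higher, Slc25a37), endothelial markers (1 of 2 lower, Egfl7), dendritic cell markers (none of 2), the neutrophil marker Mmp9 (not called), the platelet marker Itgb3 (higher) and the sex-linked gene Xist (higher). The genes named for these lists were named after their values were seen.

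The drug target itself was not called. Cxcr4 was at 145 ± 35.8 FPKM with vehicle and 177 ± 38.5 FPKM with AMD3100 (log2 0.29, limma adjusted p = 0.562, 0.154 when paired), and its ligand Cxcl12 at 8.97 ± 4.59 and 10.8 ± 4.41 FPKM, so the CXCL12 list had none of 2 measured members called. Cxcl12 also stands in the stromal marker list, and RNA of the OP9 cells was not told apart from that of the leukaemia cells. The other CXCL12 receptor, Cxcr7, stayed under the minimum of 1 FPKM. Myc, the growth regulator downstream of Notch1 in T-ALL, was at 210.2 ± 6.62 and 166 ± 46.3 FPKM (log2 -0.38, adjusted p = 0.382, 0.172 when paired), lower in 3 of 3 pairs but not called. In the paired fit the Notch1 targets Hes1 (log2 0.32), Dtx1 (log2 0.35), Sox4 (log2 0.80) and Notch3 (log2 0.74) rose. Notch1 (164 ± 7.60 and 206 ± 39.7 FPKM), the pre-T cell receptor gene Ptcra (log2 -1.02) and the IL-7 receptor gene Il7r (log2 -0.17) were not called.

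Measures of RNA composition moved together with these groups. Malat1, a long RNA retained in the nucleus, rose from 242 ± 81.8 to 676 ± 214 FPKM in the paired fit, and Xist and Kcnq1ot1 rose too (log2 1.33 and 1.02). Higher genes had longer transcripts than lower genes, with medians of 4832 and 2220 bases, and the Spearman correlation across genes of fold change with transcript length was 0.321. After a correction of each pair for length the paired count was 1267 genes. Of the 2036 genes called before it, 1125 were still called in the same direction and 7 changed sign. The cholesterol and fatty acid synthesis genes that fell then numbered 22 of 32 and the G1/S genes 33 of 44. Small RNA genes took 8.24%, 6.76% and 8.70% of the summed FPKM in the vehicle libraries and 12.6%, 10.4% and 7.51% in the AMD3100 libraries.

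The tumours labelled as Cxcr4 knockouts had less Cxcr4 RNA than any wild-type tumour. Cxcr4 was at 241, 155 and 206 FPKM in wild-type tumours 1, 2 and 4 and at 23.2, 78.9 and 21.9 FPKM in knockout tumours 5, 7 and 8. The means were 201 ± 43.4 and 41.3 ± 32.5 FPKM (SD, n = 3), a log2 change of -2.49 (SE 0.51), and the change did not pass limma's test over all genes (adjusted p = 0.986; 0.0956 to 1.00 over the alternatives). The tables count RNA over whole genes, so RNA from undeleted parts of the gene or from cells without the deletion would be included. The other CXCL12 receptor Cxcr7 and the ligand Cxcl12 were listed at 0 in all 6 tumours.

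Sex-linked genes separated the genotypes. Xist, the RNA that silences one X chromosome in female cells, was at 143, 96.4 and 147 FPKM in the wild-type tumours and at 0.829, 2.80 and 2.69 FPKM in the knockout tumours (log2 -5.43, adjusted p = 0.0125 in limma). The Y-linked genes Eif2s3y (log2 5.00) and Ddx3y (log2 4.44) were higher in the knockout tumours in the same test. The remaining called gene, the small nucleolar RNA gene Snora17, was at 183, 81.0 and 579 FPKM in the wild-type tumours and listed at 0 in all knockout tumours. These 4 were all the genes limma called among 10741, and 460 had an unadjusted p under 0.05. The groups did not overlap for 9.21% of the genes, where chance gives 10%. The count was 0 without knockout 7, 0 without knockout 8 and 1 without wild type 2 or knockout 5, and 11 with red cell content as a covariate.

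**Figure D2:**
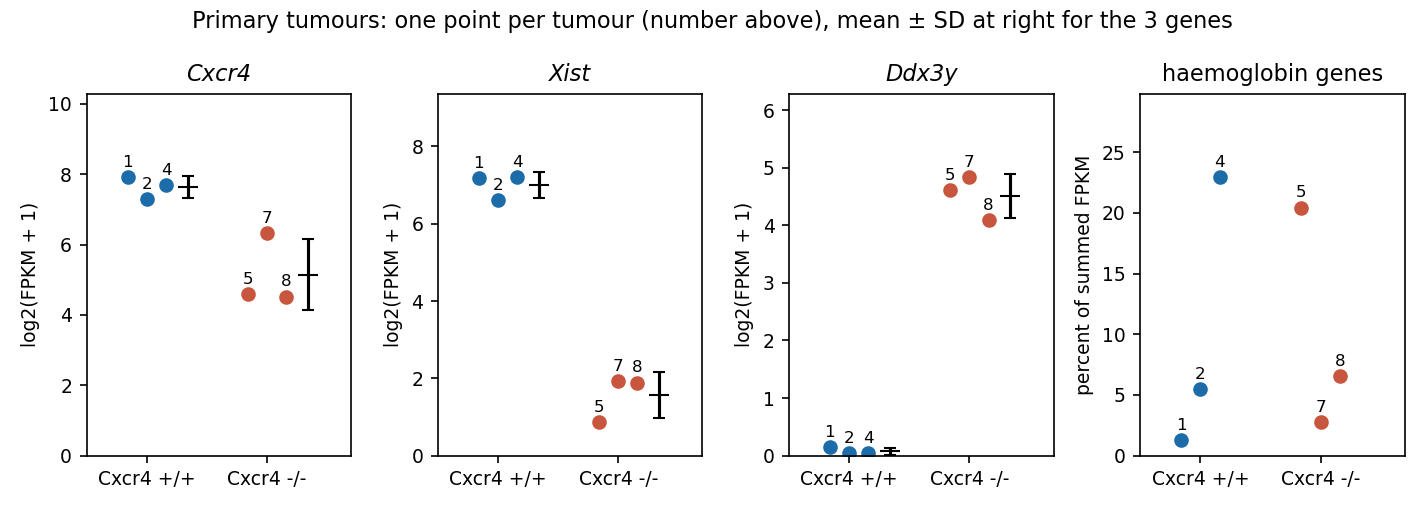
Cxcr4, Xist and Ddx3y as log2(FPKM + 1), and the percentage of summed FPKM on haemoglobin genes, in 3 wild-type and 3 knockout tumours, with the tumour number above each point and the mean with SD bars beside the 3 genes. Cxcr4 and Xist are lower and Ddx3y is higher in every knockout tumour, while haemoglobin runs from 1.29% to 23.0% with no separation of the genotypes.

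Gene groups differed between the tumour genotypes in median, while almost no single member passed the test. Genotype coincided with sex in these tumours, so no such difference can be assigned to the knockout alone. Camera called 15 of 28 lists, 9 higher and 6 lower. Splits of the same tumours that mix the genotypes gave 9 to 15 called lists. With an estimated correlation camera called none of the 15, with an adjusted p of 0.158 for the sex-linked genes and 0.638 to 0.852 for the other 14. Homing, adhesion and egress genes had a median log2 difference of 0.71 in favour of the knockout tumours over 31 members, and recombination and double-positive thymocyte genes one of -1.40 over 13 members, all 13 below 0. NK and cytotoxic markers had a median of 1.04 (15 of 15 above 0) and B cell markers one of 0.87 (7 of 7 above 0).

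Lists called higher besides these were the immediate early and NF-kB genes (39 members, median 0.41), interferon response (41, 0.36), macrophage markers (15, 0.36), cytosolic ribosomal proteins (49, 0.28), FoxO and PI3K-Akt responsive genes (23, 0.20) and the sex-linked genes. Lists called lower were G1/S and DNA replication (44 members, median -0.52), G2/M and mitosis (38, -0.38), oxidative phosphorylation (53, -0.19), Myc targets (50, -0.16) and cholesterol and fatty acid synthesis (31, -0.064). In these 15 lists limma called none of the members except the 3 sex-linked genes (2 higher, 1 lower). Adjusted over the list alone, it called 4 sex-linked genes higher and 1 lower, 3 ribosomal protein genes higher and 1 recombination gene lower. Not called were the Notch1 targets (median -0.012, 1 higher and 2 lower adjusted over the list alone), leukaemia-initiating genes (0.42), T cell receptor genes (0.35), glycolysis and hypoxia (-0.044, 1 higher adjusted over the list alone), amino acid and ER stress (0.029), p53 targets (-0.098) and heat shock (0.13). The markers of erythroid cells (0.60), neutrophils (-1.02), dendritic cells (0.36), platelets (-0.44), stroma (-0.34) and endothelium (0.36) were not called either. With 1 tumour or another left out, camera did call the Notch1, leukaemia-initiating, T cell receptor, amino acid, heat shock, erythroid, neutrophil and dendritic cell lists, the erythroid and neutrophil markers higher or lower depending on the tumour. Of the CXCL12 list only Cxcr4 was measured, and it was lower when adjusted over the list alone. The number of lists called fell to 9 without knockout 7. The Myc, G2/M, oxidative phosphorylation, cholesterol and macrophage calls had an adjusted p of 0.0479 and held in only 9 to 11 of 22 other settings, with G2/M turning direction without wild type 4 or knockout 7 and macrophage markers with array weights or without wild type 4. The FoxO and G1/S calls were lost without wild type 2, wild type 4 or knockout 7, the interferon call without wild type 1 or knockout 5 and the B cell call without wild type 4.

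Values of single genes behind these medians were not called, with limma adjusted p between 0.306 and 1.00. Il7r was at 19.7 ± 10.0 FPKM in wild-type and 78.6 ± 26.9 FPKM in knockout tumours, Klf2 at 78.9 ± 34.4 and 238 ± 86.4 FPKM, S1pr1 at 46.2 ± 30.5 and 128 ± 74.4 FPKM and S1pr4 at 17.8 ± 10.3 and 59.6 ± 24.9 FPKM. Dntt, the terminal transferase of V(D)J recombination, was at 197 ± 180.3 and 18.0 ± 6.41 FPKM, Arpp21 at 41.4 ± 47.9 and 3.79 ± 2.27 FPKM and the IL-2 receptor chain gene Il2ra at 84.4 ± 55.3 and 11.9 ± 5.33 FPKM. Among the Notch1 targets, Notch3 had a log2 difference of -2.58, Hes1 of -1.48, Notch1 of -1.01 and Dtx1 of 0.35. Myc was at 77.8 ± 30.0 and 78.6 ± 29.5 FPKM. Rpl12 had the largest difference among ribosomal protein genes (log2 3.69), a value that is uncertain because ribosomal protein genes have many pseudogene copies. Neutrophil markers were highest in wild-type tumour 2 (mean log2 5.33) and T cell genes in wild-type tumour 1 (mean log2 8.18 against 6.26 to 7.67 in the others).

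Drug and knockout were compared over the 9646 genes measured in both tables. No gene was called by limma in both comparisons without pairing. Only 2 tumour calls, both lower, were among these genes. Independent lists would share 0 higher and 0.00166 lower genes, so this absence of shared calls decides nothing. With the AMD3100 samples paired, Xist was called in both, higher with AMD3100 and lower in the knockout tumours, and no gene was called in both in the same direction. At an unadjusted p under 0.05 in each, 35 genes were higher in both, where independent lists would share 18.9, and 43 were lower in both, against 25.8 (one-sided Fisher's exact p = 0.000226 and 0.000451, across genes that are not independent). With the paired AMD3100 calls the shared numbers were 49 against 19.5 and 50 against 21.3. In the tumours only 189 of the 9646 genes were higher and 205 lower at that threshold, together a smaller share than the 0.05 chance gives. Fisher's test treats genes as independent, so it does not exclude chance for these overlaps. Across genes, the fold changes of the 2 comparisons had a Pearson correlation of 0.204 and a Spearman correlation of 0.256, and leaving out single libraries moved the Pearson correlation from 0.112 (without wild type 4) to 0.289 (without wild type 1). Homing, immediate early and interferon genes were called higher by camera, and G1/S, G2/M, Myc target, oxidative phosphorylation and cholesterol genes lower, in both comparisons, and none of them with an estimated correlation (adjusted p between 0.291 and 0.852). The difference between the comparisons was not tested for any list. Because genotype coincided with sex in the tumours, a shared change cannot be assigned to the loss of Cxcr4 alone.

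**Figure D3:**
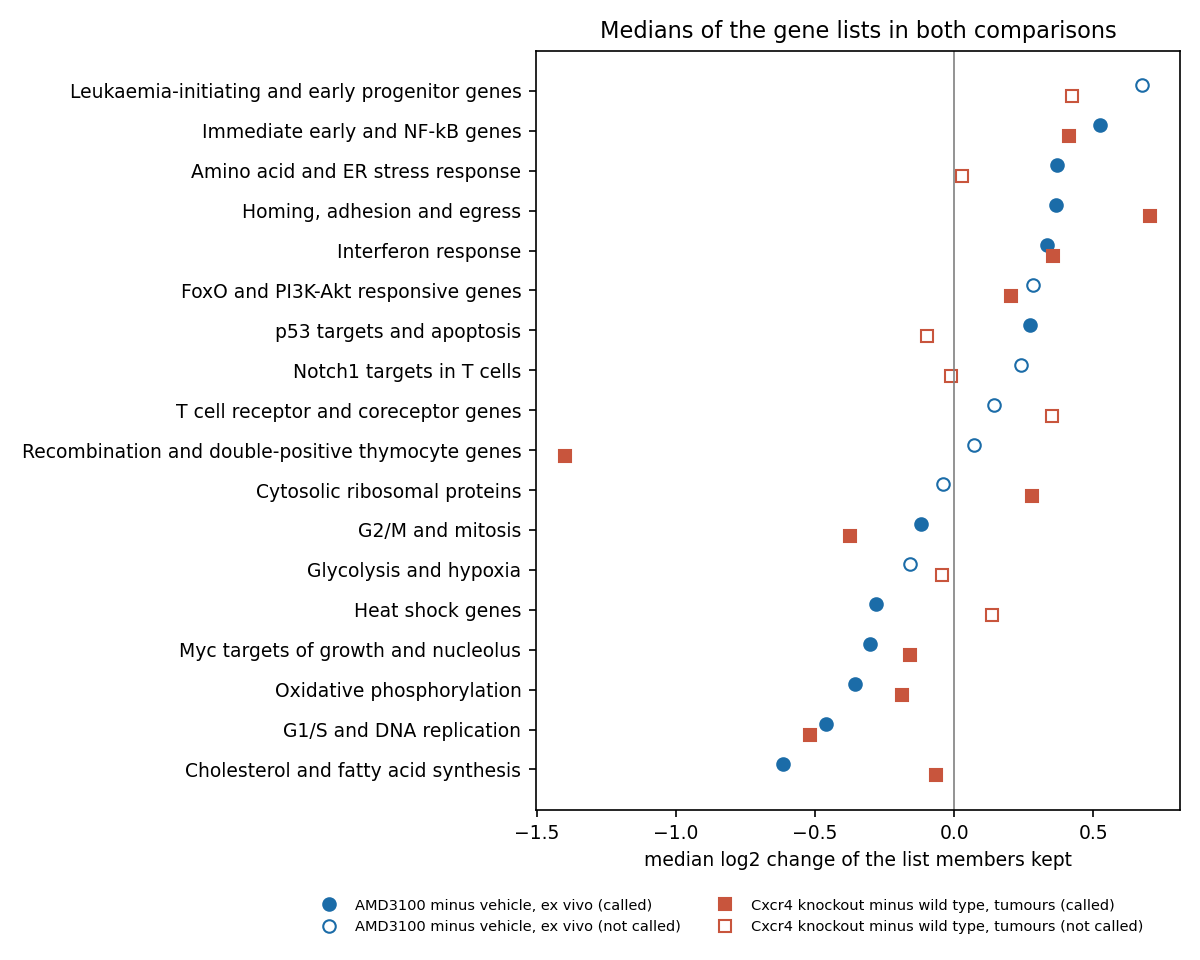
Median log2 change of the measured members of 18 gene lists with AMD3100 against vehicle ex vivo (circles) and in Cxcr4 knockout against wild-type tumours (squares), filled where camera with a preset correlation called the list. Cholesterol and fatty acid synthesis genes are lowest with AMD3100 (-0.61), and recombination genes are lowest in the knockout tumours (-1.40).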

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

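The nuclear RNA, sex and mislabelling tests and the count of pair-keeping combinations were chosen only after the results were seen, and the paired length and GC corrections, the red cell covariate and the omission of the tumours richest in red cell RNA are alternatives added after seeing the data.

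The log2 change of Xist with AMD3100 exceeded its change in the knockout tumours by 6.76 (1.33 against -5.43), and the 3 samples of each group lay apart from the other group in both comparisons, in opposite directions. The difference for Stip1, a heat shock co-chaperone whose groups also lay apart in both, was -1.01 (-0.51 against 0.50). Neither difference was tested, and drug and knockout are different contrasts in different material. Ex vivo, Xist was at 45.0 to 160 FPKM in every library, and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty stayed under 1 FPKM. The ex vivo change of Xist is therefore one of level, while in the tumours Xist and the Y-linked genes separated the genotypes, so the 2 changes are of unlike kinds.

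The paired AMD3100 comparison called 2036 genes, with a trend of fold change on transcript length and a rise of nuclear-retained RNAs. GC content is argued against as the cause, since 2026 genes were called after its removal, and length is argued against for the lipid and amino acid lists, whose medians after correction were -0.68 and 0.39. For the whole set length stays open, because 1267 genes were called after the correction, between the bounds set beforehand for and against it. A higher share of nuclear RNA in the AMD3100 samples may contribute, as the 5 measured nuclear RNAs of 15 listed had a median change of 1.02 and 4 of them rose, and such a share could come from treatment, cell state or RNA extraction. An action of AMD3100 on these genes remains open beside it and was not tested apart from it.

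Sex-linked genes separated the tumour genotypes: for 5 of 5 the groups did not overlap. A single mislabelled tumour is argued against, as 0 tumours lay on the other genotype's side of the midpoint for Xist or Cxcr4. Wild-type tumours from female mice and knockout tumours from male mice are a candidate explanation for the 5 genes. Differences between the genotypes in any other gene cannot then be told apart from differences of sex by this design, and an effect of the knockout on those genes remains open.

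Few genes were called between the tumour genotypes although Cxcr4 itself differed by -2.49. Red cell RNA that differs between tumours may have widened the spread, since 11 genes were called with the erythroid score as a covariate against 4 without it, although 3 were called when the tumours richest in red cell RNA, wild type 4 and knockout 5, were left out, a fit with fewer samples, so this too stays open. The low number of genes above 0 in knockout tumour 8 stays open, with 0 genes called without it. The bound written beforehand took a count that falls as evidence against this explanation; it was dropped after the value was seen, because a fit with 1 tumour fewer can lose calls without any such deficit (the count was 3 without wild type 1, 1 without wild type 2, 4 without wild type 4, 1 without knockout 5 and 0 without knockout 7), so a fall decides nothing. A true similarity of the genotypes also remains open, and in simulated tumours only 2 of 100 genes changed by 1 on the log2 scale were recovered.

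With 3 samples against 3, the 10 splits are too few to give a share under 0.05. For the ex vivo genes the real split gave 13 and the highest other 2 (1 of 10 as large), and with pairs kept 2036 and 2 among 4 relabellings, where the others swap the drug within 1 pair. For the ex vivo lists the values were 11 and 12, and for the tumour lists 15 and 15 (2 of 10 as large in each). The other splits called from 3 to 12 ex vivo lists and from 9 to 15 tumour lists. Camera at its preset correlation thus called lists in every split that mixes the groups. For the tumour genes the real split gave 4 and the highest other 725 (2 of 10 as large). That split set wild type 1, knockout 7 and knockout 8 against the rest, which points to a structure of the samples other than genotype. These tumours had the highest mean log2 of T cell genes (8.18, 7.67 and 7.11). It was 6.26, 6.34 and 6.51 in wild type 2, wild type 4 and knockout 5. Their erythroid mean was the lowest (4.54, 6.81 and 7.99 against 8.39, 9.78 and 9.81). Cell composition is thus partly mixed with genotype. With the erythroid score as a covariate camera called 14 tumour lists at its preset correlation, and no list test adjusted for T cell content. For the correlation of 0.204 between the comparisons, 4 of 100 combinations of splits were as far from 0 (highest other 0.269). Of the 40 combinations that keep the ex vivo pairs, 4 were as far from 0, so chance is not excluded. The other 3 joined the real ex vivo split to another split of the tumours.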

How the results depend on the processing

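The paired fits with other settings and the alternatives on small RNAs, red cells and T cell content were chosen after seeing the data; the causes of the shifts were not tested unless the setting itself shows them. The direction of Cxcr4 between tumours held in all 22 alternatives, from -3.08 (without knockout 7) to -2.03 (array weights), without passing the threshold in any. The ex vivo count of 13 became 8 with no filter, 188 at a mean of 5 FPKM, 89 with median-of-ratios scaling, 3 with quantile normalisation, 1 without the mean trend, 692 with array weights, 847 at an adjusted p under 0.10, 4 at a log2 change of at least 1 (a stricter rule), and 3 to 5 without single libraries. With the replicate block it was 2036, and in paired fits 2579 without small RNAs, 2029, 2015 and 1914 with median-of-ratios, TMM and quantile scaling, 2040 at a pseudocount of 0.1, 2108 at a mean of 5 FPKM, 1267 after length and 2026 after GC correction; without a pair it was 9, 7 or 1207. The block added 3 lists and turned no list. The tumour count of 4 became 0 with no filter, 0 to 4 without single tumours, 11 with the erythroid covariate and 0 when centred on T cell genes. No paired analysis was possible because the tumour genotypes share no replicate numbers.

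With an estimated correlation camera called 0 of the 11 ex vivo and 0 of the 15 tumour lists, and fry called 6 and 1, or 0 ex vivo with the replicate block (smallest adjusted p = 0.0702). The 11 ex vivo lists kept their direction in all 32 settings, and without single libraries 10 to 14 lists were called ex vivo and 9 to 16 in the tumours. In the tumours, G2/M and macrophage lists turned direction in 2 settings each. The correlation between the comparisons ran from 0.112 to 0.289 without single libraries, and the number of genes called in both in the same direction stayed at 0 in 26 of 26 alternatives. So few genes were called in the tumours that independent lists would share 0 higher and 0.00166 lower genes in the main fits, so this count decides nothing. Myc in the tumours (0.014) was -0.053 with TMM scaling, -0.38 with array weights, -0.012 with the erythroid covariate, -0.15 when centred on T cell genes and -0.26 to 0.32 without single tumours (below 0 without wild type 1, knockout 7 or knockout 8). Ex vivo, Il7r was 0.085 with array weights. Without single libraries or pairs Il7r ran from -0.53 to 0.33 (above 0 without vehicle 3 and, when paired, without the third pair), Cxcl12 from -0.14 to 0.73 and Klf2 from -0.23 to 2.51 (both below 0 without vehicle 3). Among the other values of named genes ex vivo, 1302 kept their side of the threshold, 528 passed it and 106 lost it; in the tumours these were 1078, 1 and 30. The robust variance model was not run for camera. The tumour tables allow no estimate of depth, which limits what their low values can show.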

Other observations

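The histone group, the genes Nkg7, Runx3, Maf, Cd7 and Ltb, and the genes shared by both comparisons were chosen after their values were seen, so the counts describe these samples and are not independent tests.

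Most measured histone genes, many of which are transcribed in S phase, fell with AMD3100. Of 47 measured histone genes, 32 fell, 1 rose and 14 were not called in the paired fit, with a median log2 change of -0.60. Without pairing, 2 fell and none rose. Hist1h4d, a histone H4 gene, was at 1184 ± 124 FPKM with vehicle and 631 ± 90.1 FPKM with AMD3100 (SD, n = 3). The gene that rose was Hist2h2be, an H2B gene known to be polyadenylated (log2 0.71). In the tumours none of 48 histone genes was called, with a median of -0.65. Most histone transcripts lack a poly-A tail, so their level in poly-A selected libraries reflects selection as well as abundance, and near-identical copies can share reads.

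Nkg7, Runx3, Maf, Cd7 and Ltb were higher with AMD3100 in 3 of 3 pairs, and were not tested as a group. Nkg7, a cytotoxic granule gene, was at 37.2 ± 7.72 FPKM with vehicle and 144 ± 104 FPKM with AMD3100 (log2 1.72). Runx3, a transcription factor of the CD8 lineage, rose from 5.17 ± 2.10 to 15.7 ± 7.32 FPKM, Maf from 3.97 ± 2.06 to 12.3 ± 3.67 FPKM, Cd7 from 19.6 ± 6.65 to 44.1 ± 9.77 FPKM and lymphotoxin beta (Ltb) from 23.2 ± 3.59 to 50.3 ± 11.5 FPKM. All 5 were called in the paired fit and none without pairing. In the tumours Nkg7 was at 352 ± 255 FPKM in wild-type and 665 ± 316 FPKM in knockout samples, and was not called.

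Among the genes with an unadjusted p under 0.05 in both comparisons and the same direction, Ccnd2, which encodes cyclin D2, was at 41.7 ± 17.1 FPKM in wild-type and 129 ± 57.5 FPKM in knockout tumours and rose by 0.89 on the log2 scale with AMD3100. Lfng, a glycosyltransferase that modifies Notch receptors, had log2 changes of 1.19 with AMD3100 and 1.76 in the tumours, and Id2, an inhibitor of E proteins, of 0.79 and 1.27. Ada, adenosine deaminase, had changes of -0.74 and -2.91, and the desaturase gene Scd2 of -0.58 and -1.49. None of them was called in the tumours after adjustment in limma.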
